A study of Mus musculus with 4 samples.

How the data were processed

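The series measured polyadenylated RNA by sequencing in lung ILC2s of IL-33-treated mice, 2 WT and 2 KO libraries, each from 200000 sorted cells pooled from 3 to 12 mice. The deposited table holds whole-number read counts per gene, not normalized, for 27179 genes named by NCBI Gene ID, and its sheet name carries the word female. Per the submitters' processing notes, fastp, HISAT2 2.2.1, featureCounts 2.0.1 and edgeR 3.34.0 were used with the mouse build mm10. The role and settings of each tool, the gene annotation and whether reads were counted by strand are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical paralogs and pseudogenes may have been lost or shared.

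Gene symbols came from a RefSeq table of GRCm38.p6, the same build as mm10, which named 25275 Gene IDs, and GENCODE M21 named 18 more. The 1886 Gene IDs left without a symbol held 0.558% of the counts and stayed in the fits. No read was counted in 8182 genes. Coordinates are those of GRCm38.p6, counted from 1. Of 725 entries in 33 gene lists, 711 matched the table. The list of 13 mitochondrially encoded genes and Hbb-bt were not analysed here.

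Libraries were grouped by the genotype in their labels, and the deposited counts were compared between KO and WT with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, with factors of 0.982 and 0.995 for WT and 0.990 and 1.034 for KO replicates 1 and 2. The filter filterByExpr at its minimum count of 10 kept 13383 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, a gene was called at an adjusted p under 0.05, and adjusted p-values in the report are from this test unless camera is named. Levels are CPM, counts scaled to a common library total with TMM factors, computed from the deposited counts, and errors are the SD of 2 libraries or the SE of the log2 fold change. The labels call the libraries biological repeats of pooled mice, so the spread is between pools, not between mice. The counts of replicate libraries differed by more than sampling noise (chi-square per degree of freedom 41.2 for WT and 35.1 for KO). This spread exceeds that of the same library counted again, but it cannot show that the pools were independent. Each library was used as a replicate because the labels call it a biological repeat. Depth was near equal between libraries, with 25872460 to 26108077 counts.

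Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01, for the 29 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. Camera asks whether the members shift in 1 direction against the other genes, so members that move both ways can cancel. Counts of list members are given over all genes tested and adjusted over the list alone. The lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule named 15 genes always, the 8 called genes that moved most in each direction with separated libraries, a mean of at least 10 CPM and a symbol that is not a predicted or pseudogene name, up to 4 called members of each list by adjusted p, and for a list without a call its 2 members with the highest mean. For lists of other cell types or RNA quality it allowed at most 2 members. It gave 74 genes, of which 41 were called; 1 that was not called is not reported here.

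The alternatives were RLE size factors, library totals alone, no filter beyond 1 read, filters of 1 CPM in 2 libraries and of a mean of 10 CPM, DESeq2 1.42.0, limma-voom, the edgeR exact test, the replicate number as a block, each library left out in turn, and for the lists camera with an estimated correlation and fry. With DESeq2 and the exact test, the lists were tested by the preranked form of camera. It used signed z-scores from the p-values of the genes in place of log2 CPM, with the same preset correlation. The fit was tested on simulated counts for the comparison of KO with WT, drawn from the means and library sizes of the data for 13214 genes. It recovered 81% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 8 false calls among 189 (4.2%). The changed genes were drawn only from genes with mean counts well above the filter. The recovery of genes with few reads was therefore not tested. A raised simulated list was called, and 0 of 28 lists without a change were. The simulated genes were drawn independently of each other, so this could not test the preset correlation on lists whose members move together. In the data the estimated correlation of the MHC class II list was 0.45. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.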

Results

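Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that answer epithelial alarm cytokines such as IL-33 by making IL-5 and IL-13. Polyadenylated RNA was sequenced from lung ILC2s of mice given 500 ng of IL-33 into the peritoneum, with 4 days stated for the treatment. The cells were sorted as lineage-negative, CD45-positive and RFP-positive. All mice carried a Cre recombinase at the Il5 locus. They had either wild-type Smarca4 (WT, n = 2 libraries) or floxed Smarca4 on both alleles (KO, n = 2 libraries). Each library came from 200000 cells pooled from 3 to 12 mice. The total count was 25880474 and 26108077 in WT replicates 1 and 2, and 25872460 and 25962946 in KO replicates 1 and 2. Between 16981 and 17246 genes had at least 1 read in a library, and the 10 highest genes took 5.55% to 6.38% of the counts. The first principal component held 54.7% of the variance and placed both WT libraries (-24.1 and -30.2) apart from both KO libraries (31.2 and 23.0).

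The comparison asked how ILC2s differ when Smarca4, which encodes the BRG1 ATPase of the BAF (SWI/SNF) chromatin remodelling complexes, is targeted. Smarca4 (NCBI Gene ID 20586, chromosome 9, 21616106 to 21704230, mm10) stood at 280 and 293 CPM in the WT libraries and at 73.2 and 99.1 CPM in the KO libraries. The KO libraries thus held 25.5% and 34.6% of the WT mean, and the fall was 3.33-fold (log2 -1.73 ± 0.17 SE, adjusted p = 0.00493). The labels do not say which exons are floxed, and gene-level counts take in reads from exons left in place. Smarca2, which encodes the alternative ATPase BRM, had 113 ± 5.29 CPM in WT and 126 ± 10.8 in KO (SD, n = 2 each; log2 0.16, adjusted p = 0.715). Among 26 tested subunits of BAF complexes, Smarca4 was the single gene that passed, over all genes and adjusted over the list alone. The list as a whole did not shift in 1 direction against other genes (camera adjusted p = 0.769).

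In KO ILC2s, Cdh1, Il10, Irf4 and Ccr7 rose while Gzmb, Ass1, Il17a, Calca and 4 of 10 tested MHC class II genes fell. Of 13383 genes tested, 160 were higher and 131 lower in KO at an adjusted p under 0.05, and 129 and 98 of these differed at least 2-fold. Both KO libraries lay on the same side of both WT libraries for all 291 called genes. With so few libraries a call itself favours such separation, so this is no separate support for the calls. Among all tested genes 43.0% were separated in this way, where chance gives 33.3%. The counts of higher and lower genes depended on single libraries. They were 384 and 270 without WT replicate 1, 204 and 295 without WT replicate 2, 55 and 54 without KO replicate 1, and 86 and 71 without KO replicate 2. Of the 291 called genes, 75 kept their call without each library in turn. The fits with a lone library take its spread from the other genotype. The spread between libraries corresponded to a biological coefficient of variation of 15.2%.

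**Figure D1:**
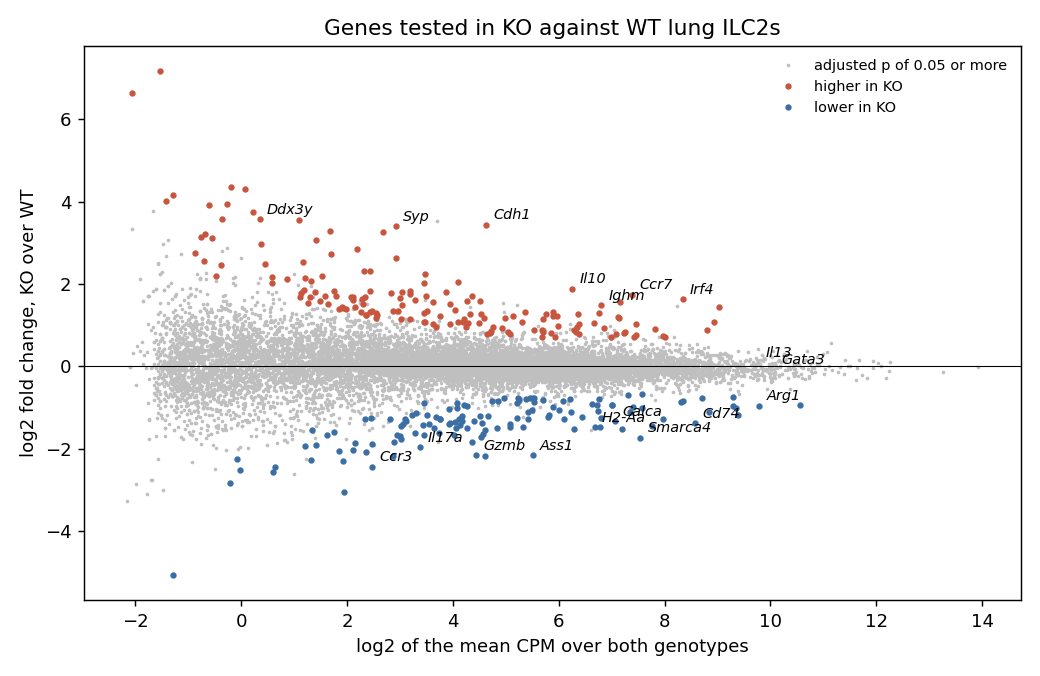
Log2 fold change of KO over WT (vertical axis) against the log2 of the mean CPM over both genotypes (horizontal axis) for the 13383 tested genes, 1 point per gene. The 160 genes higher in KO are red, the 131 lower genes are blue, the genes that did not pass are grey, and selected genes are named.

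Among genes with a mean of at least 10 CPM, the top of the higher genes was Cdh1, which encodes the adhesion protein E-cadherin (Gene ID 12550, chromosome 8, 106603350 to 106670247). It rose from 4.16 ± 1.75 to 45.2 ± 17.1 CPM (SD, n = 2 each), a 10.9-fold difference (log2 3.44 ± 0.34 SE, adjusted p = 0.00493). Zc3h12d, a gene of the family of regnase RNA-binding proteins, rose 4.71-fold (log2 2.24, adjusted p = 0.00725). Ptk2, which encodes focal adhesion kinase, rose 4.15-fold to 27.7 ± 2.26 CPM (log2 2.05, adjusted p = 0.00493). Nme4, a mitochondrial nucleoside diphosphate kinase gene, rose 4.04-fold (adjusted p = 0.0065), and Tesc, which encodes the calcium-binding protein tescalcin, rose 3.27-fold (adjusted p = 0.00726). Cd7, a lymphoid surface receptor gene, rose 3.49-fold (log2 1.80, adjusted p = 0.0227). Its call was lost without KO replicate 1 (log2 1.48, adjusted p = 0.0715).

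The ranking left out predicted genes and pseudogenes, and at its other end stood Gzmb, which encodes the cytotoxic protease granzyme B. It fell 4.48-fold from 35.3 ± 5.11 to 7.87 ± 1.79 CPM (SD, n = 2 each, log2 -2.16 ± 0.21 SE, adjusted p = 0.00493). Ass1, whose enzyme argininosuccinate synthase makes an arginine precursor, fell 4.45-fold from 74.7 to 16.8 CPM (adjusted p = 0.00493). The transcribed pseudogene Gm5424, named after its values were seen, fell 4.50-fold (log2 -2.17), and reads of near-identical copies can be split between such genes. Phf11b fell 3.58-fold (adjusted p = 0.0140). Slc6a13, a GABA transporter gene, fell 3.16-fold (log2 -1.66, adjusted p = 0.0128), with its call lost without KO replicate 2 (log2 -1.54, adjusted p = 0.0511).

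Most of the genes that define ILC2s did not pass the test. All libraries held only cells that passed the same sort, so these values do not cover cells outside that gate. Gata3, the transcription factor required for ILC2s, had 1097 ± 9.38 CPM in WT and 1041 ± 172 in KO (SD, n = 2 each; log2 -0.08, adjusted p = 0.917). Il1rl1, the IL-33 receptor gene, had 1500 and 1368 CPM (log2 -0.13, adjusted p = 0.792). Rora (log2 -0.25, adjusted p = 0.694) and Klrg1 (log2 -0.38, adjusted p = 0.577) did not pass either. Of 22 tested identity genes, 1 rose, 1 fell and 20 did not pass, and adjusted over the list alone 5 were higher and 2 lower. The gene that rose was Il18r1, which encodes a chain of the IL-18 receptor, from 54.8 ± 10.01 to 113 CPM (log2 1.04 ± 0.16 SE, adjusted p = 0.0177). The gene that fell was Arg1, the arginase of ILC2s, from 1171 ± 114 to 602 ± 79.5 CPM (log2 -0.96 ± 0.16 SE, adjusted p = 0.0222). The Il18r1 call was lost without KO replicate 1 (log2 1.04, adjusted p = 0.0558) or KO replicate 2 (log2 1.02, adjusted p = 0.0553), and the Arg1 call without KO replicate 2 (log2 -0.85, adjusted p = 0.0784). The list did not shift in 1 direction (camera adjusted p = 0.920), with a median log2 change of -0.05 and a mean of 0.02. Of its 22 tested genes 7 were at an unadjusted p under 0.05 by edgeR, beside 1900 of all 13383 tested genes. DESeq2 called 5 of them, limma-voom 2 and the exact test 6.

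Il10, which encodes an anti-inflammatory cytokine, rose and Calca, which encodes the neuropeptide CGRP, fell, while the type 2 cytokine genes did not pass in the main fit. Il10 (Gene ID 16153, chromosome 1, 131019845 to 131024970) went from 27.7 and 37.7 CPM in WT to 151 and 90.2 in KO, a 3.69-fold rise (log2 1.88 ± 0.25 SE, adjusted p = 0.01002). Calca (Gene ID 12310, chromosome 7, 114625981 to 114636910) went from 191 ± 3.99 to 75.9 ± 13.3 CPM, a 2.52-fold fall (log2 -1.33 ± 0.16 SE, adjusted p = 0.00676). Il5 had 298 ± 119 CPM in WT and 197 ± 34.8 in KO (log2 -0.60, adjusted p = 0.331). Its log2 change ran from -0.96 without WT replicate 1, where a call as lower rested on 1 WT library, to -0.14 without WT replicate 2. Il5 passed as lower in the edgeR fit with the replicate number as a block (log2 -0.55, adjusted p = 0.00439). Nothing says that these numbers mark a shared batch. All mice carried a Cre recombinase at the Il5 locus, and how this affects the Il5 counts was not tested. Il13 had 841 ± 547 CPM in WT and 899 ± 363 in KO (log2 0.10, adjusted p = 0.962). Its direction turned without WT replicate 1 (log2 -0.46) or KO replicate 2 (log2 -0.41), and it passed as higher without WT replicate 2 (log2 0.97, adjusted p = 0.00512). Csf2 (log2 0.16, adjusted p = 0.843) and Areg (log2 -0.15, adjusted p = 0.854) did not pass. Of 21 tested cytokine and effector genes, Il10 was higher, Calca lower and 19 did not pass, and adjusted over the list alone 5 were higher and 3 lower. The list as a whole did not shift in 1 direction (camera adjusted p = 0.738). Of its 21 tested genes 9 were at an unadjusted p under 0.05 by edgeR, and DESeq2 called 3, limma-voom 2 and the exact test 4.

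**Figure D2:**
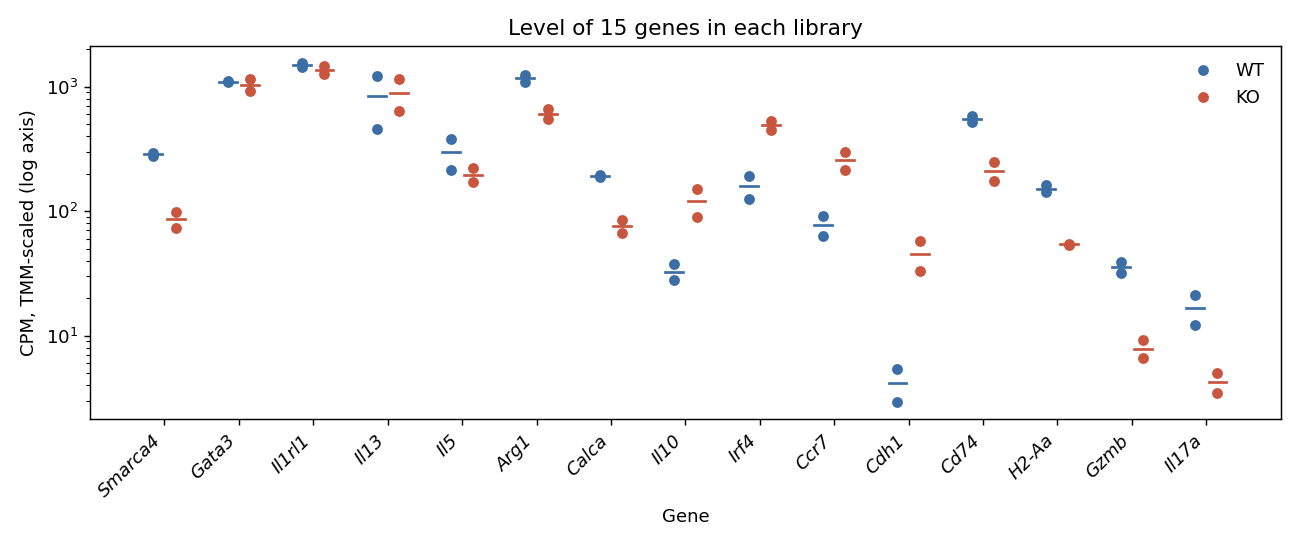
TMM-scaled CPM on a log axis for 15 genes (horizontal axis), with 1 point per library, WT in blue and KO in red, and a bar at the mean of the 2 libraries. Il10 lay at 27.7 and 37.7 CPM in WT and at 151 and 90.2 in KO, while the Il13 values of the genotypes overlapped.

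Of 10 tested MHC class II genes, whose products load and present peptide antigen to CD4 T cells, 4 fell and 6 did not pass. The list passed as lower in KO (camera adjusted p = 3.48e-11). With an estimated correlation camera gave p = 0.0806 and adjusted p = 0.944, and fry gave p = 0.0123 and adjusted p = 0.178. H2-Aa (Gene ID 14960, chromosome 17, 34282744 to 34287823) went from 151 ± 13.7 to 54.0 ± 0.442 CPM (SD, n = 2 each; log2 -1.48 ± 0.14 SE, adjusted p = 0.00493). H2-Ab1 went from 162 ± 23.1 to 58.8 ± 9.48 CPM (log2 -1.47, adjusted p = 0.0065) and H2-Eb1 from 116 ± 13.0 to 40.3 ± 4.70 CPM (log2 -1.53, adjusted p = 0.00493). Cd74, which encodes the invariant chain, went from 550 ± 43.4 to 212 ± 52.997 CPM (log2 -1.38 ± 0.19 SE, adjusted p = 0.0108). Adjusted over the list alone all 10 were lower, with a median log2 change of -1.32. Ctss, which encodes a lysosomal protease of antigen-presenting cells, fell as well, from 48.3 ± 1.59 to 26.3 ± 0.361 CPM (log2 -0.88, adjusted p = 0.0222). The Ctss call was lost without KO replicate 1 (log2 -0.89, adjusted p = 0.0978) or KO replicate 2 (log2 -0.88, adjusted p = 0.0875).

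The list of type 1 and cytotoxic lymphocyte genes passed as lower in KO (camera adjusted p = 0.0426). With an estimated correlation camera gave p = 0.160 and adjusted p = 0.944, and fry gave p = 0.0824 and adjusted p = 0.341. Nkg7, a cytotoxic granule gene, fell with Gzmb, from 24.9 ± 11.7 to 7.81 ± 1.61 CPM (SD, n = 2 each; log2 -1.67 ± 0.32 SE, adjusted p = 0.0361). It lost its call without KO replicate 1 (log2 -1.90, adjusted p = 0.0631) or KO replicate 2 (log2 -1.49, adjusted p = 0.127) and by limma-voom (log2 -1.60, adjusted p = 0.0593). Tbx21, the gene of the type 1 transcription factor T-bet, was near silent at 0.680 CPM in WT and 0.549 in KO (adjusted p = 0.883). Of 15 tested members, none rose, these 2 fell and 13 did not pass, and adjusted over the list alone 1 was higher and 3 lower. The list also lost its call without WT replicate 1 (adjusted p = 0.0654), WT replicate 2 (adjusted p = 0.0571) or KO replicate 2 (adjusted p = 0.392), with RLE scaling (adjusted p = 0.0503) and with no filter on low counts (adjusted p = 0.225). Of the natural killer cell markers 2 were tested, Gzma (log2 -0.74, adjusted p = 0.450) and Prf1 (log2 -1.50, adjusted p = 0.144), too few for a list test. By edgeR 1 was at an unadjusted p under 0.05 and, adjusted over these 2 alone, lower. Gzma passed as lower without WT replicate 2 (log2 -1.11, adjusted p = 0.00403), and its log2 change ran from -0.25 without KO replicate 2 to -1.51 without KO replicate 1. The exact test called Prf1 (adjusted p = 0.0446), and DESeq2 and limma-voom called 0 of the 2.

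Il17a, the type 3 cytokine gene, fell 3.91-fold from 16.6 ± 6.21 to 4.25 ± 1.11 CPM (SD, n = 2 each; log2 -1.97 ± 0.31 SE, adjusted p = 0.0186), with the call lost without KO replicate 2 (log2 -1.74, adjusted p = 0.0594). Of 13 tested type 3 genes, Il17a was lower and 12 did not pass, and adjusted over the list alone 2 were higher and 5 lower. This list did not shift in 1 direction (camera adjusted p = 0.486), with a median log2 change of 0.05 and a mean of -0.18. Of its 13 tested genes 7 were at an unadjusted p under 0.05 by edgeR, and DESeq2 called 3, limma-voom 1 and the exact test 3.

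Ccr7, the receptor that guides lymphocytes to lymph nodes, Ccr4 and Itgae rose, and none of the tested migration and adhesion receptors passed as lower. Ccr7 (Gene ID 12775, chromosome 11, 99144199 to 99155077) went from 77.1 ± 19.4 to 257 ± 61.7 CPM (SD, n = 2 each; log2 1.74 ± 0.22 SE, adjusted p = 0.00834). Ccr4, a chemokine receptor of type 2 lymphocytes, went from 130 ± 5.99 to 221 ± 1.75 CPM (log2 0.77, adjusted p = 0.0236). Itgae, which encodes the CD103 integrin that binds E-cadherin, went from 35.6 ± 11.7 to 82.6 ± 6.59 CPM (log2 1.22, adjusted p = 0.0286). Without KO replicate 1 the calls of Ccr4 (log2 0.78, adjusted p = 0.0961) and Itgae (log2 1.29, adjusted p = 0.0558) were lost, as they were without KO replicate 2 (log2 0.75 and 1.12, adjusted p = 0.0962 and 0.0896). Of 30 tested receptors 27 did not pass, and adjusted over the list alone 5 were higher and 2 lower (camera adjusted p = 0.920, median log2 -0.01, mean 0.06). By edgeR 8 of them were at an unadjusted p under 0.05, and DESeq2 called 7, limma-voom 3 and the exact test 7. Among 22 memory and quiescence genes Ccr7 alone passed, and adjusted over the list alone 5 were higher and none lower (camera adjusted p = 0.173). Of these 22 genes 10 were at an unadjusted p under 0.05 by edgeR, and DESeq2 called 4, limma-voom 1 and the exact test 5. Without WT replicate 1 this list passed as higher (camera adjusted p = 0.0327).

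Irf4, Nr4a3 and Myc rose and Dusp2 fell among 27 tested immediate early and AP-1 genes, which lymphocytes switch on soon after stimulation. Irf4, a transcription factor gene of activated lymphocytes (Gene ID 16364, chromosome 13, 30749233 to 30766981), went from 158 ± 45.7 to 490 ± 54.8 CPM (SD, n = 2 each; log2 1.63 ± 0.21 SE, adjusted p = 0.00834). Nr4a3, an orphan nuclear receptor gene, went from 158 to 295 CPM (log2 0.90, adjusted p = 0.0309) and Myc from 109 to 192 CPM (log2 0.81, adjusted p = 0.0433). Dusp2, which encodes a MAP kinase phosphatase, went from 26 to 10.3 CPM (log2 -1.33, adjusted p = 0.0193). Without KO replicate 1 the calls of Nr4a3 (log2 0.95, adjusted p = 0.0766), Myc (log2 0.81, adjusted p = 0.144) and Dusp2 (log2 -1.39, adjusted p = 0.0560) were lost. They were also lost without KO replicate 2 (log2 0.83, 0.81 and -1.29, adjusted p = 0.114, 0.130 and 0.0675), and that of Myc with no filter (adjusted p = 0.0650). The counts adjusted over the list alone were the same, 3 higher and 1 lower, and the list as a whole did not pass (camera adjusted p = 0.173).

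Among 16 heat shock and dissociation stress genes, a group that responds to tissue digestion, none passed over all genes or adjusted over the list alone (camera adjusted p = 0.919). None was at an unadjusted p under 0.05 by edgeR (0 genes), and DESeq2, limma-voom and the edgeR exact test called 0. Hspa8 had 4014 ± 1863 CPM in WT and 3272 ± 130 in KO (SD, n = 2 each; log2 -0.29, adjusted p = 0.732), and Hsp90ab1 had a log2 change of -0.21 (adjusted p = 0.699). The WT libraries differed from each other in these genes. The list passed as lower in KO without WT replicate 1 (camera adjusted p = 1.38e-05) and as higher without WT replicate 2 (camera adjusted p = 6.33e-05), and Hspa8 passed as lower without WT replicate 1 (log2 -0.71, adjusted p = 0.0154). Of 25 inhibitory receptor and regulatory genes, Il10 rose and 24 did not pass. Adjusted over the list alone 4 were higher and 2 lower (camera adjusted p = 0.738, median log2 -0.03, mean 0.01). Of these 25 genes 11 were at an unadjusted p under 0.05 by edgeR, and DESeq2 called 4, limma-voom 1 and the exact test 4.

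The alarmin receptor and NF-kB pathway genes gave no call among 29 members by either adjustment, with 2 at an unadjusted p under 0.05 by edgeR and 1 called by DESeq2, 0 by limma-voom and 1 by the exact test (camera adjusted p = 0.738). Tnfaip3, an NF-kB feedback gene, had 4045 ± 618 CPM in WT and 4294 ± 189 in KO (SD, n = 2 each; log2 0.09, adjusted p = 0.896), and Nfkbia had a log2 change of 0.04 (adjusted p = 0.957). None of 40 cell cycle and DNA replication genes passed by either adjustment, with 3 at an unadjusted p under 0.05 by edgeR and 0 called by the other 3 tools. Mki67 had 821 ± 204 and 773 ± 150 CPM (log2 -0.09, adjusted p = 0.927) and Top2a had 568 and 588 CPM (log2 0.05, adjusted p = 0.959). The cell cycle list did not pass (camera adjusted p = 0.482), but passed as lower without WT replicate 2 (camera adjusted p = 0.0478) or KO replicate 1 (camera adjusted p = 0.0147). None of 29 apoptosis and p53 target genes passed by either adjustment, where 6 were at an unadjusted p under 0.05 by edgeR and DESeq2 and the exact test each called 2 and limma-voom 0, with Birc3 at a log2 change of -0.27 (adjusted p = 0.439) and Trp53inp1 at 0.10 (adjusted p = 0.900). That list did not shift in 1 direction (camera adjusted p = 0.551).

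Of the metabolic lists, glycolysis and hypoxia (camera adjusted p = 0.0110), fatty acid and lipid droplet (camera adjusted p = 0.0110) and oxidative phosphorylation genes (camera adjusted p = 0.00841) passed as lower in KO. In that order they had adjusted p = 0.944, 0.944 and 0.977 with an estimated correlation. None of 26 glycolysis and hypoxia genes passed singly, and 4 were lower adjusted over the list alone. By edgeR 7 of them were at an unadjusted p under 0.05, and DESeq2 and the exact test each called 3 and limma-voom 0. Ldha, the lactate dehydrogenase gene, had 1578 ± 130 CPM in WT and 1085 ± 12.0 in KO (SD, n = 2 each; log2 -0.54, adjusted p = 0.108), and Pkm had a log2 change of 0.07 (adjusted p = 0.919). Ldha passed as lower without WT replicate 1 (log2 -0.63, adjusted p = 0.0376), by DESeq2 (adjusted p = 0.0130) and by the exact test (adjusted p = 0.0473). The median of this list was -0.13. Fads2, a fatty acid desaturase gene, was the single member of 28 fatty acid and lipid droplet genes that fell, from 5.09 to 1.68 CPM (log2 -1.60, adjusted p = 0.0459). Adjusted over the list alone 1 was higher and 1 lower. The list median was -0.18. Fads2 was not called without WT replicate 2 (log2 -1.24, adjusted p = 0.0974), KO replicate 1 (log2 -1.73, adjusted p = 0.124) or KO replicate 2 (log2 -1.48, adjusted p = 0.159), with no filter (adjusted p = 0.0549), with the filter of 1 CPM in 2 libraries (adjusted p = 0.0507) or by limma-voom (adjusted p = 0.0614).

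None of 32 oxidative phosphorylation genes passed by either adjustment, and 3 were at an unadjusted p under 0.05 by edgeR while the other 3 tools called 0, with Atp5b at a log2 change of -0.23 (adjusted p = 0.541) and Atp5a1 at -0.17 (adjusted p = 0.706). The median was -0.15. Without KO replicate 2 the glycolysis (adjusted p = 0.0759), fatty acid (adjusted p = 0.0632) and oxidative phosphorylation (adjusted p = 0.375) lists lost their calls. Without WT replicate 2 the fatty acid (adjusted p = 0.0670) and oxidative phosphorylation (adjusted p = 0.184) lists did, and a filter at a mean of 10 CPM ended the fatty acid call (adjusted p = 0.0830). None of 24 cholesterol synthesis genes passed by either adjustment, and 2 were at an unadjusted p under 0.05 by edgeR while DESeq2 and the exact test each called 1 and limma-voom 0 (camera adjusted p = 0.173), with Srebf2 at a log2 change of -0.13 (adjusted p = 0.776) and Cyp51 at -0.28 (adjusted p = 0.538). Without WT replicate 1 this list passed as lower (camera adjusted p = 0.000704).

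Interferon response genes were lower in KO as a list, with a median log2 change of -0.24 over 33 tested members (camera adjusted p = 0.00454). With an estimated correlation camera gave p = 0.244 and adjusted p = 0.977, and fry gave p = 0.223 and adjusted p = 0.588. Ifitm3, which encodes an antiviral membrane protein, fell from 12.5 ± 1.32 to 4.95 ± 0.861 CPM (SD, n = 2 each; log2 -1.33 ± 0.22 SE, adjusted p = 0.0229) and was the single member that passed, with 3 lower and none higher adjusted over the list alone. Without KO replicate 1 neither Ifitm3 (log2 -1.17, adjusted p = 0.102) nor the list (adjusted p = 0.223) was called.

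**Figure D3:**
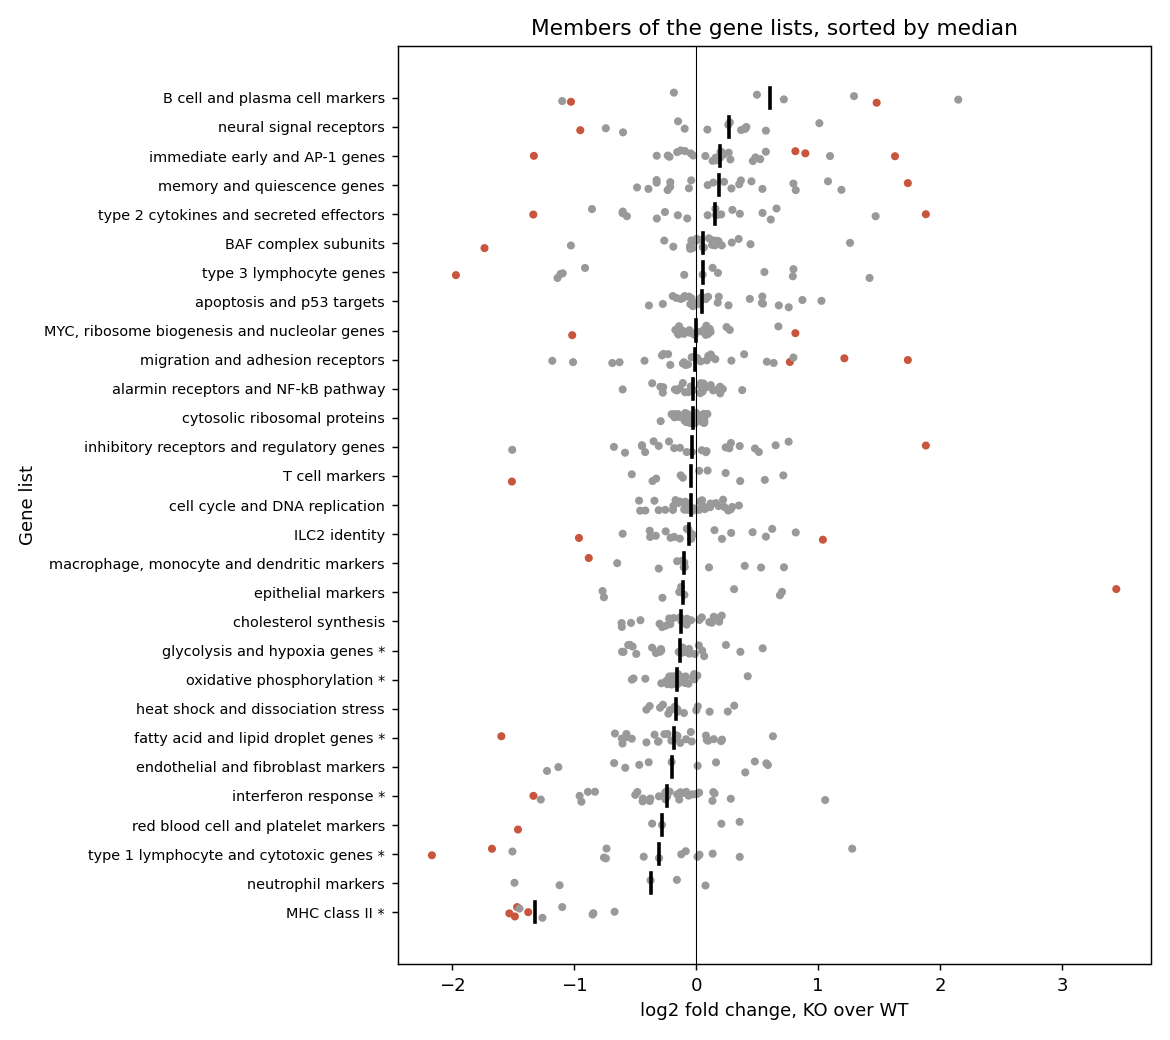
Log2 fold change of KO over WT (horizontal axis) of the tested members of 29 gene lists (vertical axis, sorted by median), with 1 point per gene and a black bar at the list median. Red points are genes that passed over all genes, and a star marks the 6 lists called by camera with the preset correlation, none of which was called with an estimated correlation. MHC class II lay lowest, with a median of -1.32.

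Ptgir, which encodes the prostacyclin receptor, fell from 169 ± 2.37 to 87.6 ± 15.2 CPM (SD, n = 2 each; log2 -0.95, adjusted p = 0.0216) and was the single call among 14 tested receptors of neural and lipid signals. Adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.486). Odc1, the polyamine synthesis enzyme and a known MYC target, fell from 877 ± 96.0 to 434 ± 114 CPM (log2 -1.01, adjusted p = 0.0382), while Myc rose. These were the 2 calls among 26 MYC, ribosome biogenesis and nucleolar genes by either adjustment. The list as a whole did not shift in 1 direction (camera adjusted p = 0.937, median log2 0.00, mean 0.02). This list passed as lower without WT replicate 1 (camera adjusted p = 0.0234) and as higher without WT replicate 2 (camera adjusted p = 0.0478). Without KO replicate 1 the calls of Ptgir (log2 -0.78, adjusted p = 0.107), Odc1 (log2 -0.77, adjusted p = 0.125) and Myc (log2 0.81, adjusted p = 0.144) were lost, and that of Myc also without KO replicate 2 (log2 0.81, adjusted p = 0.130) and with no filter (adjusted p = 0.0650). None of 37 cytosolic ribosomal protein genes passed by either adjustment, with 0 at an unadjusted p under 0.05 by edgeR and 0 called by the other 3 tools (camera adjusted p = 0.449), with Rpl4 at a log2 change of 0.01 (adjusted p = 0.988) and Rps6 at -0.05 (adjusted p = 0.951). The sign of Rpl4 turned with RLE scaling (log2 -0.0002). The ribosomal list passed as lower without KO replicate 1 (camera adjusted p = 0.00420).

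Markers of other cells that the sort could hold were measured next, beginning with lymphocytes. Cd28, a T cell costimulatory receptor gene, fell from 28.5 ± 6.12 to 10.02 ± 2.63 CPM (SD, n = 2 each; log2 -1.51, adjusted p = 0.0190) and lost its call without KO replicate 2 (log2 -1.28, adjusted p = 0.0585). It was the single call among 12 tested T cell markers, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.929). The T cell list passed as lower without WT replicate 2 (camera adjusted p = 0.0485). Ighm, which encodes the IgM heavy chain, rose from 59.1 ± 4.49 to 165 ± 19.2 CPM (log2 1.48 ± 0.15 SE, adjusted p = 0.00493), while Cd79b, a chain of the B cell receptor, fell from 22.8 to 11.2 CPM (log2 -1.02, adjusted p = 0.0480). Of 8 tested B and plasma cell markers 6 did not pass, and adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.462). The B cell list passed as higher without WT replicate 2 (camera adjusted p = 0.0478). The Cd79b call was lost without KO replicate 2 (log2 -0.80, adjusted p = 0.170), with no filter (adjusted p = 0.0664), with the filter of 1 CPM in 2 libraries (adjusted p = 0.0541) and with that of a mean of 10 CPM (adjusted p = 0.0550).

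Among myeloid markers, Ccr3, the eotaxin receptor of eosinophils, fell from 9.43 ± 0.314 to 1.74 ± 0.301 CPM (SD, n = 2 each; log2 -2.43 ± 0.26 SE, adjusted p = 0.00493). Cpa3, a mast cell and basophil protease gene, fell from 35.7 ± 16.6 to 10.8 ± 2.02 CPM (log2 -1.72, adjusted p = 0.0281), with its call lost without KO replicate 1 (log2 -1.55, adjusted p = 0.106) or KO replicate 2 (log2 -1.94, adjusted p = 0.0537). Only 4 of the eosinophil, basophil and mast cell markers had enough reads to be tested, Ccr3 and Cpa3 were the 2 that passed, and no list test was made. Of 12 tested macrophage, monocyte and dendritic markers Ctss alone passed by either adjustment (camera adjusted p = 0.669). Of 5 tested neutrophil markers none passed, 1 was at an unadjusted p under 0.05 by edgeR and the other 3 tools called 0 (camera adjusted p = 0.369), with S100a9 at 2.07 and 2.19 CPM (adjusted p = 0.976) and Csf3r at 1.29 and 0.995 CPM (adjusted p = 0.922). The neutrophil list passed as lower without WT replicate 1 (camera adjusted p = 0.00233). Ctss was not called without KO replicate 1 (adjusted p = 0.0978) or KO replicate 2 (adjusted p = 0.0875).

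Cdh1 was the single call among 10 tested epithelial markers (camera adjusted p = 0.663; median log2 -0.11, mean 0.30), and the list passed as higher without WT replicate 1 (camera adjusted p = 0.0177). None of 13 endothelial and fibroblast markers passed by either adjustment, 1 was at an unadjusted p under 0.05 by edgeR and the other 3 tools called 0 (camera adjusted p = 0.663), with Pecam1 at a log2 change of -0.20 (adjusted p = 0.730) and Pdgfrb at -0.47 (adjusted p = 0.489). Hba-a1, an alpha globin gene with the near-identical copy Hba-a2 and therefore uncertain, fell from 11.9 to 4.34 CPM (log2 -1.46, adjusted p = 0.0466) and was the single call among 5 red blood cell and platelet markers (camera adjusted p = 0.352). Its call was lost without KO replicate 1 (log2 -1.07, adjusted p = 0.129), with no filter (adjusted p = 0.0607) and with the filter of 1 CPM in 2 libraries (adjusted p = 0.0530). The Y-linked genes Ddx3y (0.194 CPM in WT and 2.37 in KO, log2 3.57, adjusted p = 0.00934) and Eif2s3y (0.116 and 1.45 CPM, log2 3.58, adjusted p = 0.0232) were higher in KO, while Xist had 1697 and 1750 CPM (adjusted p = 0.953). Ddx3y moved to a log2 change of 4.26 without WT replicate 2, and Eif2s3y to 2.88 without WT replicate 1 and 5.03 without WT replicate 2. Eif2s3y was not called without KO replicate 1 (log2 3.43, adjusted p = 0.102) or KO replicate 2 (log2 3.71, adjusted p = 0.0594).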

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

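All alternatives were planned. Smarca4 stayed called in each, with log2 changes from -1.53 (without KO replicate 1) to -1.98 (without KO replicate 2). No called gene changed sign in any setting where it was tested, and 20 of the 41 called named genes kept their call in every setting that tested them. The other 21 each lost it without a KO library, and Fads2 also without WT replicate 2. Of these 21, Myc, Fads2, Cd79b and Hba-a1 also lost it with no filter, Fads2, Cd79b and Hba-a1 with the filter of 1 CPM in 2 libraries, Cd79b with that of a mean of 10 CPM, and Nkg7 and Fads2 by limma-voom, with a highest adjusted p over all settings of 0.170 for Cd79b. Of the 291 calls, RLE scaling kept 290, library totals 289, no filter 229, the filter of 1 CPM in 2 libraries 263, that of a mean of 10 CPM 175, DESeq2 283, limma-voom 272 and the exact test 291. The counts of higher and lower genes were 86 and 94 at a mean of 10 CPM, where 8540 genes were tested (52 and 60 at least 2-fold), 271 and 239 by DESeq2, and 413 and 302 by the exact test (255 and 189 at least 2-fold). The cause of the larger counts was not tested. Leaving out 1 library gave 55 to 384 higher and 54 to 295 lower genes, 55 to 265 and 54 to 197 of them at least 2-fold, and 2 to 13 called lists, with fewer samples in each fit. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05), and fry called 0 (3 at an unadjusted p under 0.05), against 6. For the glycolysis list the estimated correlation was -0.03, below the preset 0.01, yet its camera p went from 0.00176 to 0.07295. With 4 libraries the estimated form has few degrees of freedom, so its lack of calls cannot be put down to correlation alone. Over all settings, with the highest value from the estimated correlation, the adjusted p of the MHC class II list ran from 3.66e-29 to 0.944, of type 1 genes from 0.00324 to 0.944, of glycolysis from 0.00164 to 0.944, of fatty acid genes from 0.00407 to 0.944, of oxidative phosphorylation from 0.000408 to 0.977 and of interferon genes from 1.32e-05 to 0.977.

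Genotypes share replicate numbers, but nothing says that these mark a shared batch, and there are 2 pairs. The differences between replicates 1 and 2 correlated at 0.277 across genes between the genotypes, and the second principal component (29% of the variance) separated the numbers. With the replicate number as a block, 846 genes were higher and 651 lower (350 and 273 at least 2-fold), all 291 calls were kept and 6 lists were called. Il5 (log2 -0.55), Ldha (log2 -0.54), Gzma (log2 -0.81) and Prf1 (log2 -1.49) then passed.

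These genes turned sign when 1 library was left out, with these lowest and highest log2 changes. The ranges were -0.44 to 0.20 for Areg, -0.15 to 0.55 for Csf2, -2.05 to 1.47 for Csf3r, -0.27 to 0.0827 for Gata3, -0.43 to 0.0268 for Hsp90ab1, -0.71 to 0.27 for Hspa8 and -0.46 to 0.97 for Il13. They were -0.33 to 0.19 for Mki67, -0.0647 to 0.13 for Nfkbia, -0.42 to 0.0361 for Pecam1, -0.0225 to 0.14 for Pkm, -0.53 to 0.0756 for Rora, -0.10 to 0.10 for Rpl4 and -0.22 to 0.086 for Rps6. They were -0.62 to 1.46 for S100a9, -0.96 to 0.13 for Tbx21, -0.0743 to 0.25 for Tnfaip3, -0.23 to 0.26 for Top2a and -0.11 to 0.29 for Trp53inp1. Rpl4 also turned with RLE and with DESeq2 (log2 -0.0002 in each).

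Some lists not called by camera also changed direction, and the values that follow are adjusted p. When 1 library was left out the ranges were 0.531 to 0.908 for BAF subunits, 0.588 to 0.980 for ILC2 identity, 0.0234 to 0.378 for MYC and nucleolar genes, 0.0485 to 0.524 for T cell markers, 0.114 to 0.744 for alarmin and NF-kB genes, 0.0147 to 0.672 for cell cycle and 0.000704 to 0.781 for cholesterol synthesis. They were 0.00420 to 0.812 for ribosomal proteins, 0.196 to 0.656 for endothelial and fibroblast, 0.0177 to 0.880 for epithelial, 1.38e-05 to 0.816 for heat shock, 0.143 to 0.943 for inhibitory receptor, 0.0927 to 0.608 for macrophage, 0.00233 to 0.516 for neutrophil, 0.114 to 0.816 for type 2 cytokine and 0.169 to 0.980 for type 3 genes. Direction also turned with no filter for T cell markers (0.995), at a mean of 10 CPM for ILC2 identity (0.982), inhibitory receptors (0.851) and MYC genes (0.923), by DESeq2 for BAF subunits and ILC2 identity (0.965 each) and by limma-voom for MYC genes (0.972). It did so by the exact test for BAF subunits (0.994) and ILC2 identity (0.970), and by fry for ILC2 identity, heat shock and MYC genes (0.978 each). Apart from the construction of the settings, the cause of these turns was not tested. Memory genes (0.0177 to 0.977 over all settings), immediate early genes (0.0134 to 0.944) and B cell markers (0.0190 to 0.977) passed as higher by DESeq2, which gave each lowest value, and by the exact test, and the B cell markers also with the filter of 1 CPM in 2 libraries. With DESeq2 and the exact test the list statistic changed along with the tool, from log2 CPM to signed z-scores. The effects of tool and statistic on the lists cannot be told apart.

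At 25872460 to 26108077 counts per library, 2 to 5 members of the lists of natural killer, eosinophil, neutrophil and red blood cell markers had enough reads to be tested, and no other depth was tried.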

Other observations

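All genes in these 2 opening paragraphs were picked after their values were seen, no enrichment was tested for them as groups, and each kept its edgeR call without each library in turn. Afdn, which encodes the junction scaffold afadin, rose from 11.5 ± 0.622 to 34.3 ± 1.42 CPM (SD, n = 2 each; log2 1.58, adjusted p = 0.00493), and Cttn, the cortactin gene, from 21.2 to 49.6 CPM (log2 1.23, adjusted p = 0.00876). Nckap1, a subunit of the WAVE actin regulator, rose from 6.27 to 18.4 CPM (log2 1.55, adjusted p = 0.0075). Against them, Cald1, the caldesmon gene, fell from 6.88 to 0.818 CPM (log2 -3.06, adjusted p = 0.00493), and Enah, which encodes an actin filament elongation factor, from 23.6 to 9.29 CPM (log2 -1.34, adjusted p = 0.00834). Syp, the gene of the synaptic vesicle protein synaptophysin, rose from 1.31 ± 0.158 to 13.9 ± 0.328 CPM (log2 3.41, adjusted p = 0.00344) and Insyn1, an inhibitory synapse gene, from 1.21 to 11.7 CPM (log2 3.27, adjusted p = 0.00452).

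The chemokine gene Cxcl10 rose from 72.5 ± 6.65 to 213 ± 14.6 CPM (SD, n = 2 each, log2 1.55, adjusted p = 0.00493). Tnfrsf8, which encodes CD30, rose from 86.4 to 196 CPM (log2 1.18, adjusted p = 0.00557), and S100a6 from 279 ± 44.1 to 763 ± 279 CPM (log2 1.45, adjusted p = 0.0230). Alox5, which encodes the leukotriene-forming 5-lipoxygenase, fell from 216 ± 1.51 to 75.5 ± 7.36 CPM (log2 -1.52, adjusted p = 0.00493), Jag1, a Notch ligand gene, from 42.1 to 14.9 CPM (log2 -1.50, adjusted p = 0.0114), and the eotaxin gene Ccl24 from 12.3 to 3.80 CPM (log2 -1.70, adjusted p = 0.0124). The linker histone genes H1f0 (104 to 47.8 CPM, log2 -1.12, adjusted p = 0.00848) and H1f2 (145 to 68.2 CPM, log2 -1.09, adjusted p = 0.00814) fell too.

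All tests of explanations that follow were chosen after the results were seen. Of 10 tested MHC class II genes 4 passed as lower in KO, with Cd74 at a log2 change of -1.38. Cells of other types that present antigen, carried over into the WT libraries, are argued against as the whole source: the 20 tested members of the lists of macrophage, monocyte and dendritic and of B and plasma cell markers had a median log2 change of -0.0942 (SD 0.84), with 9 above and 11 below 0, and the 11 with at least 1 CPM in WT had -0.11 (SD 0.79), with 3 above and 8 below 0. Of their more abundant members Ctss (48.3 to 26.3 CPM) and Cd79b (22.8 to 11.2 CPM) fell with Cd74, Chil3 had 23.5 and 22.0 CPM, Lyz2 had 2.64 and 2.85 CPM and Ighm rose, and the lineage gate would remove most such cells. A source with Ctss and Cd79b but few of the other markers stays open, as does an effect of the genotype within the sorted cells, which was not tested. Markers of eosinophils, basophils and mast cells were not part of this test. Of the 4 tested, Ccr3 (log2 -2.43) and Cpa3 (log2 -1.72) fell with Cd74 and 2 did not pass, so a source of those types stays open too.

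Y-linked genes had 22 reads in the WT libraries together and 249 in the KO libraries, while the sheet name carries the word female and Xist had 1697 CPM in WT and 1750 in KO. Reads of the X-linked partners assigned to the Y copies at a constant share would give a ratio near 1. The ratio of Y-linked to X-linked partner reads was 11.73 times as high in KO (95% counting interval 7.59 to 18.15), which argues against them. Ddx3y and Eif2s3y, which prompted the test, are part of this ratio, so its size was partly set by that choice. Kdm5d and Uty, which did not prompt the test, had 6 reads in WT, 10 in KO replicate 1 and 39 in KO replicate 2, with ratios to partner reads 3.68 (1.34 to 10.13) and 11.94 (5.05 to 28.22) times those of WT, as a small share of male cells or of reads from a male library would give. Ddx3y had 60 and 64 reads and Eif2s3y 41 and 35 in KO replicates 1 and 2, so the genes differed in how they were shared between these libraries, and whether 1 male source accounts for all of them stays open. The intervals cover counting error only, and no biological explanation was tested.

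Cdh1 rose from 4.16 to 45.2 CPM. Epithelial cells carried over in KO are argued against as its source, because the 9 other tested epithelial markers had a median log2 change of -0.12 (SD 0.54), with 3 above and 6 below 0, beside 3.44 for Cdh1, and the CD45 gate would remove such cells. Other explanations were not tested.

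Replicate 1 of both genotypes held more reads of some T cell genes than replicate 2. Cd4 had 6.65 CPM in WT replicate 1 and 0.693 in WT replicate 2, and 5.39 and 2.09 CPM in KO replicates 1 and 2. Of the B cell markers, Igkc had 4.45 CPM in WT and 10.9 in KO (log2 1.29, edgeR adjusted p = 0.0769).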
